A study of Mus musculus with 6 samples.

How the data were processed

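Total RNA was isolated from activated mouse CD8 T cells and sequenced in 6 libraries, 3 from cells treated with NaCl and 3 from cells treated with DAHB. Per the submitters' processing notes, Trimmomatic 0.36, STAR 2.5.2b, featureCounts 1.5.2 and DESeq2 were used with the GRCm38 build; the version of DESeq2, the annotation release and the strand setting were not given in the sources used here. Without a stated strand setting, reads of a gene and of an antisense or overlapping partner cannot be told apart. Slc5a3 lies within the span of Mrps6 on the same strand, so the values of both are uncertain whatever the strand setting. The values deposited by the authors are a normalised signal, read counts per gene divided by 1 size factor per library. In each library 100% of the values were whole multiples of the value of 1 read within a tolerance of 0.001, which gave back whole reads and the depth of each library, between 31055613 and 56007582 reads. The table held 13883 genes, of which 59 had no symbol. The lowest sum of reads of any gene over the 6 libraries was 61, so genes with fewer reads had been left out by a filter that is not stated, and their absence from the table is no measurement. Coordinates are those of GENCODE M21 on GRCm38, in which 13859 of the gene identifiers were found.

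Samples were grouped by the treatment in their labels, and the columns of the table were matched to samples by the library names in the labels. Pairs of libraries within a group differed by more than sampling noise (chi-square per degree of freedom 4.64 to 17.5), so each was counted as 1 sample. Genes with a normalised count of at least 10 in at least 3 libraries were kept, which left 13804. Values were transformed as log2(normalised count + 1), with a pseudocount of 1, and tested with limma-trend (limma 3.58.1 in R 4.3.3), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. All adjusted p-values of single genes are from this test unless another is named. Gene lists with at least 5 tested members were tested with camera in limma (preset correlation 0.01), adjusted over the lists; this asks whether a list stands apart from the other genes. The 44 lists, a panel of 16 T cell genes, the tests and the alternatives were fixed before the data were examined, except where a choice is said to have been made afterwards. Shares of reads per library were compared by exact permutation tests.

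The genes named are the 8 with the largest rise and the 8 with the largest fall among those past the threshold with a mean normalised count of at least 100 in the higher group and no overlap between the groups, leaving out predicted genes and those without a symbol. To these come the 16 panel genes whatever their values, and up to 4 members of each list described, taken by the largest absolute log2 fold change among members past the threshold with a mean of at least 100 in the higher group (or, where none passed, up to 2 with the highest mean). Other genes are named to account for small counts or as examples of a locus, chosen after their values were seen. Some genes that these rules take are not reported here.

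The alternatives were pseudocounts of 0.5 and 10, no filter and a minimum count of 50, quantile normalisation, equal library totals, a robust prior, the replicate number as a block, each library left out in turn, camera with an estimated correlation, and fry. On the recovered whole reads, the quasi-likelihood test of edgeR 4.0.16 called 8084 genes and DESeq2 1.42.0 called 7670, against 8071 in limma. A correction of each library for trends with GC content and exon length (13776 genes) and thinning of reads to the lowest total were added after seeing the data. Simulated data held 13377 genes, with means from the NaCl libraries, depths from all libraries and a dispersion of 0.01. Genes low with NaCl and higher with DAHB were thus simulated from their NaCl level. In these data 200 genes were changed by known folds, and the limma procedure was tested on them. It recovered 10% of the genes changed 1.25-fold, 64% of those changed 1.5-fold, 94% of those changed 2-fold and 96% of those changed 4-fold, with 7 false among 139 calls. In the simulation 200 of 13377 genes changed, whereas 8071 of 13804 were called in the data. Its dispersion was set and not estimated from these libraries. The shares recovered therefore describe the simulated setting and not the power in these data. Tables and figures were made with Python 3.11.15, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Intervals of shares are exact 95% binomial intervals and cover counting error only.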

Results

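RNA sequencing was carried out on CD8 T cells from the spleen and lymph nodes of wild-type mice. The cells were activated with antibodies to CD3 and CD28 and treated overnight with 20 mM NaCl, the control, or with 20 mM DAHB, a compound known here only by that name. Each group had 3 samples of 100000 cells. The NaCl libraries held 31929904, 31436459 and 56007582 reads counted in the genes of the deposited table, and the DAHB libraries held 31055613, 33179197 and 31378879. Nothing in the labels says that the samples of a group came from separate cultures or animals, so p-values measure only the spread between these samples, which may be technical. All samples carried the same batch label. Pearson correlations of log2 values were 0.992 to 0.995 between libraries of a group and 0.962 to 0.967 between libraries of different groups, and the first principal component, which separated the groups, held 80.2% of the variance.

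The comparison asked which mRNAs differed between activated CD8 T cells exposed to DAHB and those exposed to the same concentration of NaCl, in a study titled around mitochondrial ATP production, T cell function and chromatin accessibility. In DAHB-treated cells 13 of 23 T cell cytokine genes rose and 5 fell, 14 of 24 chemokine and chemokine receptor genes rose and 5 fell, and 10 of 15 cytotoxic effector genes rose and 3 fell. Of serine and one-carbon metabolism genes 11 of 18 fell and 1 rose, of hypoxia and HIF1 targets 17 of 25 fell and 2 rose, and of MYC target and ribosome biogenesis genes 29 of 47 fell and 4 rose. Each of these 6 lists stood apart from the other genes by camera with a preset correlation, and none did with an estimated one (adjusted p = 0.568 for each); the chemokine list was also lost under quantile normalisation (adjusted p = 0.0718). Interferon gamma mRNA (Ifng, ENSMUSG00000055170, chromosome 10, 118441046 to 118445892, GRCm38) had a normalised read count of 11233.8 ± 239.9 (SD, n = 3) with NaCl and 177465 ± 16087 (SD, n = 3) with DAHB, a log2 fold change of 3.98 (SE 0.060, adjusted p = 1.59e-14). Fold changes throughout are on the log2(normalised count + 1) scale, which understates those of genes with few reads.

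Of 13804 genes tested, 8071 changed (limma-trend, Benjamini-Hochberg adjusted p under 0.05), of which 4052 rose and 4019 fell in DAHB. Values are scaled by the size factor of each library, so rises and falls here and below are relative to the bulk of genes. The near-even split partly follows from that scaling. At least 2-fold changes were found for 1459 genes that rose and 272 that fell, so that 84.3% of these were higher in DAHB. With quantile normalisation between libraries this split was 1022 against 634 genes, or 61.7% higher. At least 8-fold changes were found for 159 genes that rose and 12 that fell. In 8750 genes, 63.4% of those tested, the libraries of the groups did not overlap, against 10% by chance for 3 against 3. The median SE of a log2 fold change was 0.08, and small differences passed the test: the smallest change called was 1.08-fold. By mean normalised count over both groups, 619 genes rose and 91 fell at least 2-fold below a mean of 50, 265 rose and 28 fell between 50 and 100, and 575 rose and 153 fell from 100 upwards. Counting changes of any size, the balance turned with abundance: 2887 genes rose and 3770 fell among those with a mean of at least 100, and 791 rose and 1762 fell from 2000 upwards, where 41 rose and 25 fell at least 2-fold.

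**Figure D1:**
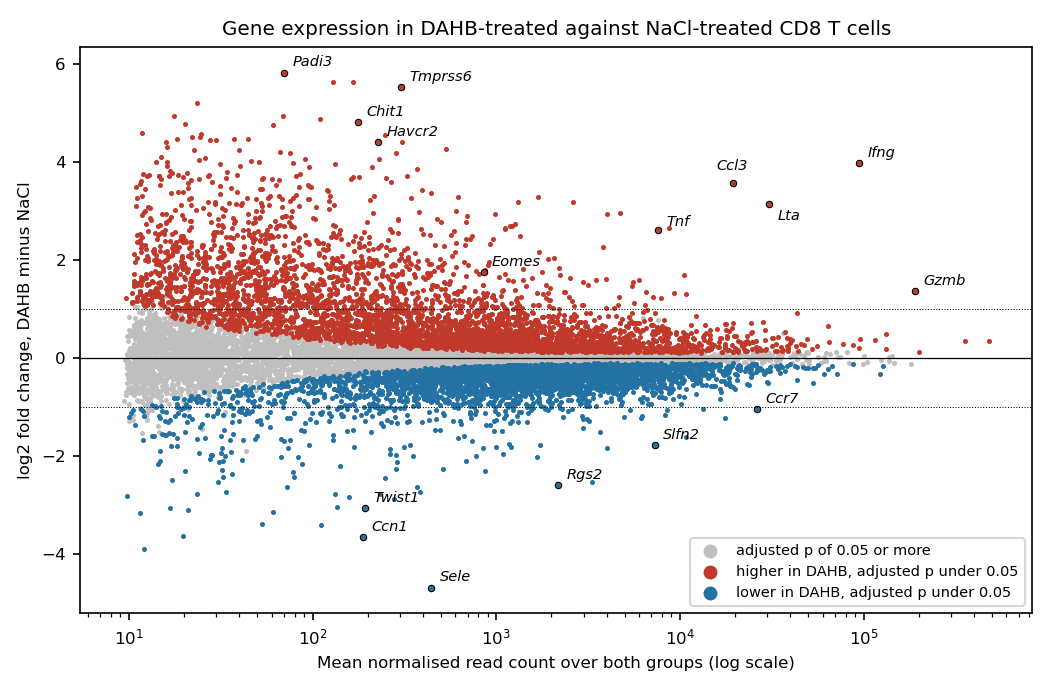
Each point is one tested gene, plotted by its mean normalised read count over both groups (log axis) and its log2 fold change of DAHB minus NaCl. Red and blue points passed an adjusted p of 0.05 (4052 higher, 4019 lower), grey points did not, and dotted lines mark a 2-fold change; Ifng, Lta and Gzmb combine a rise with very high counts.

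Among genes with a mean count of at least 100 in the higher group, Padi3, a peptidylarginine deiminase, rose from 1.52 ± 0.59 to 138.6 ± 11.4 (SD, n = 3; log2 fold change 5.82; chromosome 4, 140785365 to 140810648). The focal adhesion gene Tns4 rose from 6.18 ± 3.47 to 327 ± 30.5. The serine protease gene Tmprss6 rose from 12.1 ± 1.84 to 598 ± 26.3, and Ggt1, which encodes a gamma-glutamyltransferase, from 6.59 ± 2.90 to 212.5 ± 33.7. The chitinase gene Chit1, the p38 kinase gene Mapk13 and Stac2 rose by log2 fold changes of 4.81, 4.75 and 4.54. The largest fall by the same rule was in E-selectin (Sele, chromosome 1, 164048234 to 164057677), from 856.5 ± 137.4 to 32.4 ± 5.08, a log2 fold change of -4.68. Ccn1, a matricellular protein gene, fell from 348 ± 45.7 to 26.9 ± 4.73, Fam160a1 from 203 ± 33.5 to 19.5 ± 9.16 and Zdbf2 from 110.4 ± 16.8 to 11.7 ± 1.91. The transcription factor gene Twist1 fell from 344 ± 10.5 to 42.6 ± 17.4. Tmtc2, the adrenomedullin gene Adm and the osteoprotegerin gene Tnfrsf11b fell by log2 fold changes of -3.05, -2.88 and -2.83. The adjusted p of these genes lay between 9.58e-12 and 1.30e-07.

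Of 16 T cell genes fixed before the data were examined, 12 rose, 2 fell and 2 did not pass the test. Tumour necrosis factor (Tnf) rose from 2155 ± 118 to 13102 ± 1129 (SD, n = 3), a log2 fold change of 2.60, and interleukin 2 (Il2) from 3164 ± 147 to 5771 ± 622, a log2 fold change of 0.86. The cytotoxic protease gene Gzmb rose from 106621 ± 6464 to 275822 ± 17580.2 and the perforin gene Prf1 from 1757 ± 82.9 to 5264 ± 389. Of the T-box transcription factor genes, Eomes rose from 391 ± 17.2 to 1320 ± 48.2, a log2 fold change of 1.75, whereas Tbx21 rose by 0.20, a call that was lost after a correction for GC content and gene length (adjusted p = 0.0904). Cd8a, Tcf7, Cd69 and Il2ra rose by log2 fold changes of 0.59, 0.58, 0.58 and 0.31. The interleukin 7 receptor gene Il7r rose from 564 ± 20.7 to 1205 ± 34.1. Tox fell by a log2 fold change of -0.55. Pdcd1 was at 1814 ± 60.97 and 1885 ± 74.2 (adjusted p = 0.394) and Myc at 24184 ± 503 and 24154 ± 1353 (adjusted p = 0.964). Pdcd1 passed the test as higher under quantile normalisation (log2 fold change 0.14, adjusted p = 0.0335), and Myc passed as lower after the GC and length correction (log2 fold change -0.11, adjusted p = 0.0356).

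**Figure D2:**
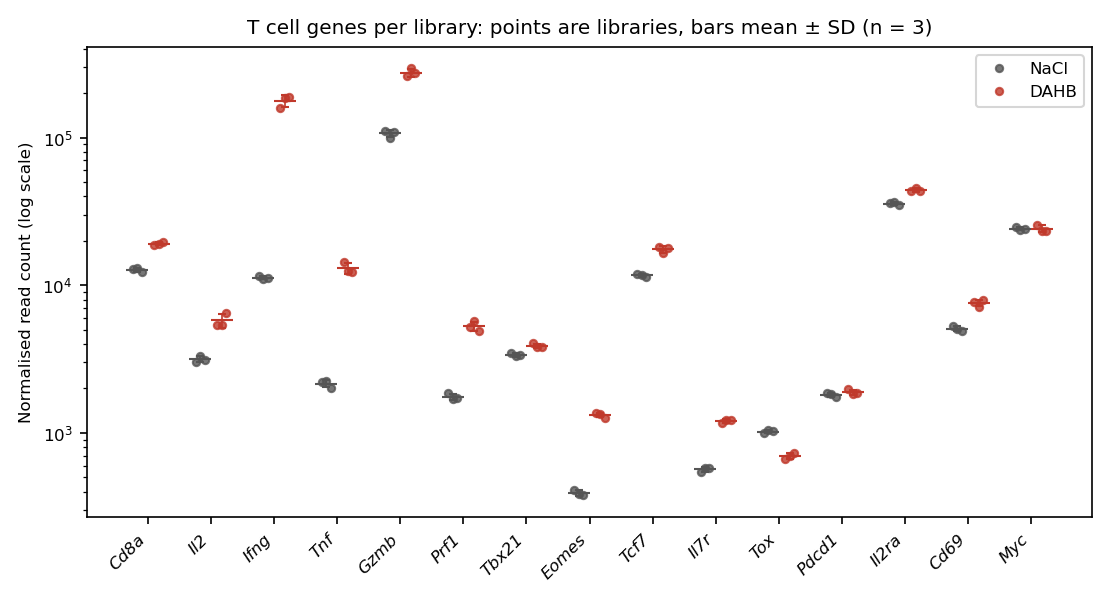
Normalised read counts (log axis) of T cell genes fixed beforehand, in NaCl (grey) and DAHB (red) libraries; points are libraries and bars are the mean ± SD (n = 3). Ifng was at 11233.8 with NaCl and 177465 with DAHB, while the libraries of both groups lay close together for Pdcd1 and Myc.

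Of 44 gene lists fixed before the data were examined, 41 had at least 5 tested members, and 12 of them stood apart from the other genes by camera with its preset correlation of 0.01. Of these 12 lists, 5 were higher and 7 lower in DAHB. None of the 12 calls held with a correlation estimated from these libraries, where the lowest adjusted p was 0.568 and 3 lists had an unadjusted p under 0.05. In that form camera also takes its degrees of freedom from the 6 libraries and no longer from all genes, so few lists can pass. For T cell cytokines the estimated correlation was -0.0072, below the preset 0.01, and for mitosis it was 0.0107, yet both lost their call. For these lists the loss therefore does not show that correlation between genes undid the call. By fry, which tests each list by itself, 30 lists passed. One other split of the 6 libraries also gave 12 lists by camera. Each other split mixes both treatments unevenly, so part of the treatment difference stays in it and it gives no level for chance. The number of lists depended on the method, so it carries little weight. The counts of members below rest on the test of each gene. The counts of members and camera were not matched on abundance. Among all 3764 genes with a mean count of at least 2000, 1762 fell and 791 rose. A majority of falls in a list of abundant genes is therefore partly shared with other abundant genes. For 34 of the 44 lists the counts of members that rose and fell were the same when adjusted over the list alone. The others are given where they differ.

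Among T cell cytokine genes, 13 of 23 rose and 5 fell (camera adjusted p = 0.00946; adjusted p = 0.568 with an estimated correlation). Besides Ifng and Tnf, lymphotoxin alpha (Lta) rose from 6234 ± 239 to 55200.0 ± 3085 and GM-CSF (Csf2) from 928 ± 129 to 7117 ± 251. The 5 that fell, named after their values were seen, were Il16 and the TNF family members Tnfsf4, Tnfsf8, Tnfsf9 and Tnfsf11, with log2 fold changes from -1.28 (Tnfsf4) to -0.34 (Tnfsf9). Of cytotoxic effector genes, 10 of 15 rose and 3 fell (11 rose adjusted over the list alone; adjusted p = 0.0126; adjusted p = 0.568 with an estimated correlation). The death ligand gene Tnfsf10 (TRAIL) rose from 207 ± 20.3 to 714 ± 58.9 and the activating receptor gene Klrk1 from 955 ± 82.4 to 2391 ± 135. Of chemokine and chemokine receptor genes, 14 of 24 rose and 5 fell (6 fell adjusted over the list alone; adjusted p = 0.0263; adjusted p = 0.568 with an estimated correlation). Ccl3 rose from 2996 ± 228 to 35765 ± 1713, Ccl1 from 23.8 ± 9.11 to 309 ± 30.5 and Ccl9 from 84.7 ± 13.5 to 675 ± 77.7. Cxcr5, the receptor that guides cells to B cell follicles, rose from 66.3 ± 10.2 to 721 ± 14.0. The chemokine list lost its call under quantile normalisation (adjusted p = 0.0718), where 12 members rose and 8 fell.

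Lists of T cell states moved in both directions and did not pass camera. Of 27 naive, stem-like and central memory genes, 16 rose and 8 fell (adjusted p = 0.104), among them Nsg2, which rose from 259 ± 18.1 to 943 ± 55.1, and Xcl1, which rose from 4947 ± 353 to 16085 ± 1689. Of 25 effector regulators, 14 rose and 6 fell (adjusted p = 0.259): Id2 rose from 1229 ± 34.2 to 3790.4 ± 238, while Zeb2 and Rora fell by log2 fold changes of -1.05 and -1.07. Of 20 tissue residency and TGF-beta response genes, 13 rose and 5 fell (adjusted p = 0.109). The integrin gene Itgae, which encodes CD103, rose from 30.8 ± 8.93 to 158 ± 13.1 and Rgs2 fell from 3745 ± 327 to 619 ± 35.7. Of 22 inhibitory receptor and exhaustion genes, 9 rose and 9 fell (adjusted p = 0.666), with a median log2 fold change of 0.05 and a mean of 0.23 although the test pointed down. TIM-3 (Havcr2) rose from 20.51 ± 7.10 to 435 ± 25.2 and CD39 (Entpd1) from 68.2 ± 17.2 to 245 ± 16.4, whereas Btla fell from 6281 ± 176 to 1777 ± 159. Of 49 activation and costimulation genes, 14 rose and 24 fell (adjusted p = 0.167; 0.0451 after the GC and length correction). Fosb and Jun, which encode AP-1 subunits, fell by log2 fold changes of -2.11 and -1.32, and Egr2 rose by 1.32. Of 21 FOXO1 target and quiescence genes, 6 rose and 10 fell (adjusted p = 0.210), with falls in Slfn2 from 11309 ± 293 to 3318 ± 333 and in Ccr7, the lymph node homing receptor, from 35577 ± 1339 to 17193 ± 680. Of 16 CD8 T cell identity genes, 6 rose and 5 fell (adjusted p = 0.703), and Cd8b1 rose by 0.51.

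Of 38 ATF4 and integrated stress response targets, 24 fell and 6 rose (adjusted p = 0.0037; adjusted p = 0.622 with an estimated correlation). The transcription factor gene Atf5 fell from 1327 ± 57.4 to 373 ± 25.5, asparagine synthetase (Asns) from 8131 ± 415 to 4385 ± 496, and Stc2 and the cystine transporter gene Slc7a11 by log2 fold changes of -1.11 and -0.86. Of 18 serine synthesis and one-carbon genes, 11 fell and 1, Ahcy, rose (adjusted p = 0.00367; adjusted p = 0.568 with an estimated correlation). Aldh1l2 fell from 232 ± 20.1 to 50.05 ± 5.99, the methionine synthase gene Mtr from 2503 ± 135 to 1391 ± 31.6, Shmt2 from 24207 ± 438 to 15569 ± 544 and Mthfd1l by a log2 fold change of -0.70. Of 25 hypoxia and HIF1 targets, 17 fell and 2 rose (adjusted p = 0.00148; adjusted p = 0.568 with an estimated correlation). Ak4 and Ndrg1 fell by log2 fold changes of -1.180 and -1.003, while P4ha2 and Car9, the latter named after its value was seen, rose by 1.49 and 1.60. Of 22 p53 targets, 14 fell and 6 rose (adjusted p = 0.0286; adjusted p = 0.568 with an estimated correlation). Plk2 fell from 2690.3 ± 103 to 660 ± 31.7 and Perp from 1727 ± 64.9 to 444 ± 23.1. The p53 call was lost under quantile normalisation (adjusted p = 0.126) and with a minimum count of 50 (adjusted p = 0.0859). Of 23 genes of the endoplasmic reticulum unfolded protein response, 12 rose and 4 fell (adjusted p = 0.0295; adjusted p = 0.568 with an estimated correlation). The chaperone gene Hspa5 rose from 49932 ± 1027 to 78114 ± 3559, Xbp1 by a log2 fold change of 0.80 and Sec24d by 1.08. The call on that list was lost with the replicate number as a block (adjusted p = 0.0518).

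Of 47 MYC target and ribosome biogenesis genes, 29 fell and 4 rose (adjusted p = 0.00124; adjusted p = 0.568 with an estimated correlation). The rRNA processing gene Utp20 fell by a log2 fold change of -0.79 and the RNA polymerase I subunit gene Polr1a by -0.61; under quantile normalisation 26 fell and 7 rose. Of 79 cytosolic ribosomal protein genes, 47 rose and 0 fell (adjusted p = 0.000187; adjusted p = 0.787 with an estimated correlation; 0.0801 by fry). Their changes were small, with a median log2 fold change of 0.16, and reads of many of them can be shared with processed pseudogenes. Rps18 rose from 29063 ± 1467 to 39077 ± 3016. After the GC and length correction 43 rose and 5 fell, under quantile normalisation 43 rose and 3 fell, and without NaCl replicate 2 there were 33 that rose and 1 that fell. Of 47 mitosis genes, 26 fell and 5 rose (adjusted p = 0.0153; adjusted p = 0.568 with an estimated correlation). Cdc20 fell from 8554 ± 99.1 to 3660.0 ± 88.0 and Ccna2 and Plk1 by log2 fold changes of -0.60 and -0.59, while the securin gene Pttg1 rose by 0.97. The mitosis call was lost under quantile normalisation (adjusted p = 0.55, 19 fell and 9 rose) and after the GC and length correction (adjusted p = 0.0916, 24 fell and 11 rose). Of 48 DNA replication genes, 24 fell and 8 rose (9 rose adjusted over the list alone), which did not pass (adjusted p = 0.0519). It passed when NaCl replicate 2 or 3 or DAHB replicate 2 or 3 was left out, with adjusted p between 0.0369 and 0.0483. Ccne2 and Mcm5 fell by log2 fold changes of -0.88 and -0.50, and under quantile normalisation 21 members fell and 14 rose.

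Of 36 ATP-dependent chromatin remodeller genes, 18 fell and 1, Smarcd3, rose (adjusted p = 0.00946; adjusted p = 0.685 with an estimated correlation). Phf10 fell from 6323 ± 84.2 to 3238 ± 197 and Chd3 from 4036 ± 337 to 2135 ± 235, and Arid2 and Srcap fell by log2 fold changes of -0.64 and -0.63. The call on the list was lost under quantile normalisation (adjusted p = 0.233). Of 28 histone acetylation and deacetylation enzymes, 10 rose and 12 fell (adjusted p = 0.703), with a median log2 fold change of -0.11, a mean of 0.00 and a test that pointed down. Hdac1 rose from 8766 ± 336 to 15869 ± 302 and Sirt1 fell from 1865 ± 37.5 to 756 ± 48.5.

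Mitochondrial lists did not pass camera. Of 77 nuclear-encoded subunits of oxidative phosphorylation, 19 rose and 21 fell (15 and 20 adjusted over the list alone; adjusted p = 0.653). Their median log2 fold change was -0.00, positive under equal totals, edgeR and quantile normalisation (0.06 under the last), and the number that rose was 9 without NaCl replicate 2 and 10 without DAHB replicate 2 or 3. Under quantile normalisation 26 of these subunits rose and 15 fell. Ndufv3 rose by 0.84 and Ndufs1 fell by a log2 fold change of -0.48. Of 13 mitochondrially encoded mRNAs, 6 rose and 0 fell (adjusted p = 0.297), with mt-Nd1 at 20429 ± 4046 and 29142 ± 2045. Without NaCl replicate 3, 3 rose and 2 fell; 2 rose without DAHB replicate 3, with a robust prior or by DESeq2; and under quantile normalisation 5 rose and 1 fell around a median of -0.00. Of 77 mitochondrial ribosomal protein genes, 18 rose and 30 fell (19 rose adjusted over the list alone; adjusted p = 0.167; 0.0451 after the GC and length correction), among them Mrpl38, which fell by a log2 fold change of -0.46. Of 23 tricarboxylic acid cycle genes, 5 rose and 12 fell (adjusted p = 0.104): Idh2 rose from 1525 ± 46.6 to 2743 ± 77.5 and Dld fell from 9125 ± 272 to 5531 ± 162.

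**Figure D3:**
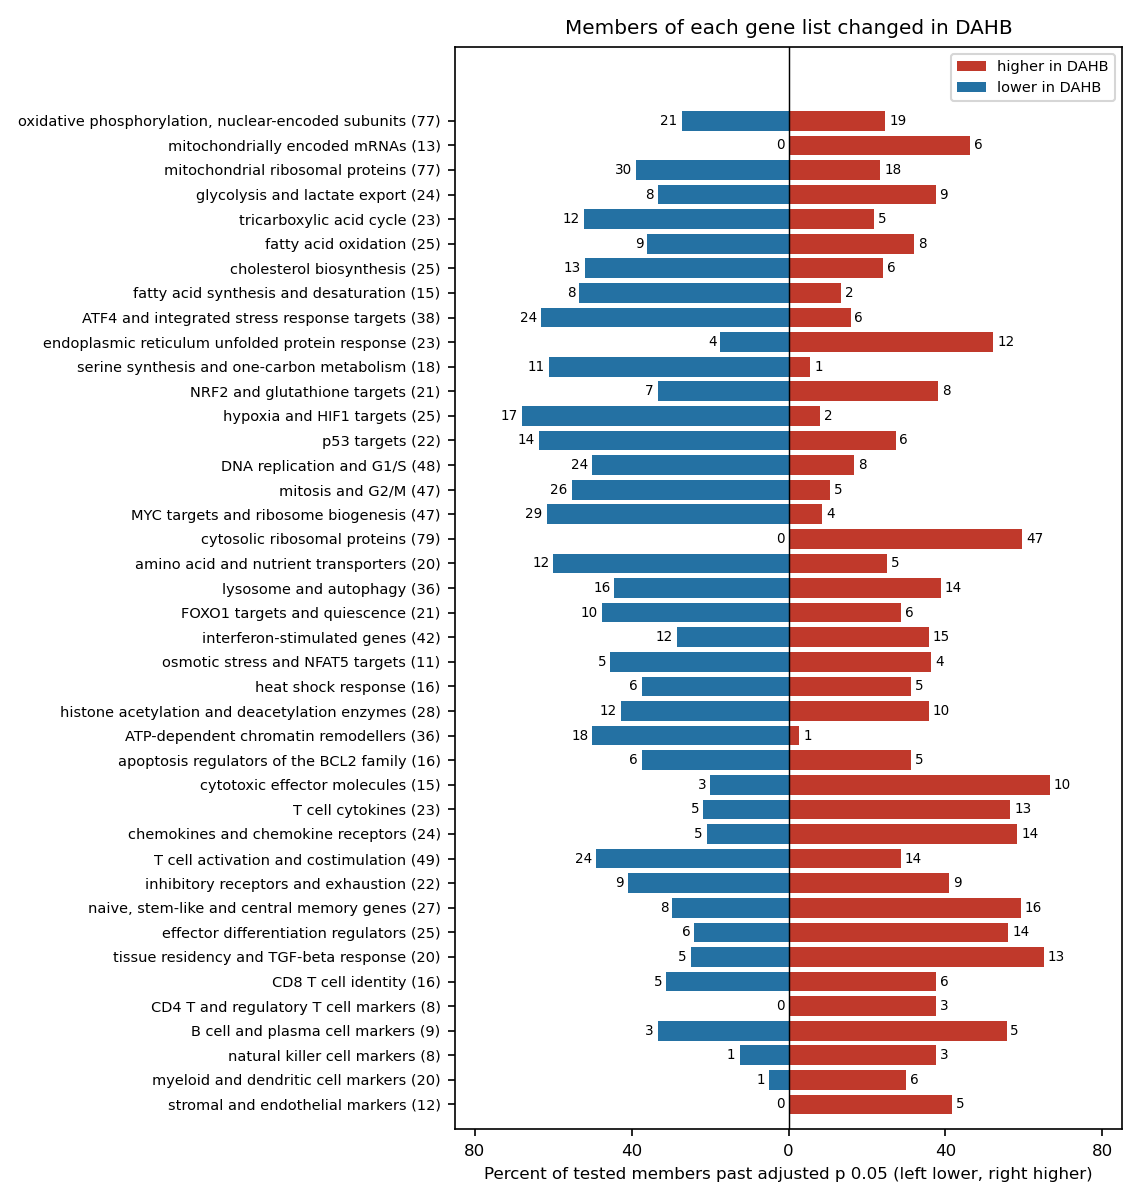
For each gene list with at least 5 tested members (number in brackets), bars give the percent of members that passed an adjusted p of 0.05 as higher (red, right) or lower (blue, left) in DAHB, with the number of genes at the bar's end. Ribosomal proteins had 47 of 79 members higher and 0 lower, and hypoxia targets 17 of 25 lower.

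Markers of other cell types also differed between the groups. Of 9 tested B cell markers, 5 rose and 3 fell (4 fell adjusted over the list alone; adjusted p = 0.252, and 0.0206 with a minimum count of 50). The class II genes H2-Aa and H2-Ab1 rose from 65.1 ± 17.7 to 317 ± 63.2 and from 177 ± 3.08 to 864 ± 64.7, and Cd79b from 133 ± 15.7 to 586 ± 37.0. The 3 that fell, named after their values were seen, were the immunoglobulin genes Ighm, Ighd and Igkc. Of 20 myeloid markers, 6 rose and 1 fell (4 rose adjusted over the list alone; adjusted p = 0.299), and 3 rose without NaCl replicate 1. Cd68 rose from 216 ± 36.4 to 448 ± 19.9. Lyz2 rose from 449 ± 144 to 699 ± 151, a call lost without NaCl replicate 1 (adjusted p = 0.0503), with a robust prior (adjusted p = 0.151) and by DESeq2 (adjusted p = 0.0931). Of 12 stromal and endothelial markers, 5 rose and 0 fell (adjusted p = 0.126). Among those that rose were Epcam, an epithelial gene that the list also holds, from 112 ± 16.2 to 366 ± 36.3, and Pdgfrb from 61.4 ± 2.32 to 195 ± 31.3. Without DAHB replicate 2, 3 rose, and under quantile normalisation 3 rose and 1 fell. The tested members do not include E-selectin (Sele), Ccn1 or Twist1, which were among the largest falls, so these counts do not cover all such genes. Of 8 CD4 and regulatory T cell markers, Cxcr5, Zbtb7b and Cd4 rose and 0 fell (adjusted p = 0.252), and Zbtb7b was at 602 ± 14.0 and 1574 ± 151; under quantile normalisation 3 rose and 2 fell. Of 8 natural killer cell markers, 3 rose and 1 fell (adjusted p = 0.400), and under quantile normalisation 1 rose and 2 fell. Ribosomal protein genes took 7.997 ± 0.316% of reads with NaCl and 8.88 ± 0.37% with DAHB, mitochondrially encoded genes 0.585 ± 0.129% and 0.770 ± 0.069%, and the 10 most abundant genes 5.61 ± 0.12% and 6.78 ± 0.20% (SD, n = 3; two-sided exact permutation p = 0.1 for each, the smallest that 3 against 3 allows).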

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

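The GC and length correction and the thinning of reads were chosen after seeing the data. The number of changed genes stayed within 1.5 times of 8071 under every alternative run: 7350 with a minimum count of 50, 8139 with quantile normalisation, 8399 after the GC and length correction, 7985 with thinned reads, and 7300 to 8324 with each library left out. The number changed at least 2-fold was 1141 instead of 1731 with a minimum count of 50, of which 948 instead of 1459 rose; this alternative tests fewer genes (11299), and the genes it removes are those of low abundance. Quantile normalisation gave 634 instead of 272 genes at least 2-fold lower; it makes the distributions of the libraries equal, but the cause was not tested further. Similar counts do not mean the same genes: under quantile normalisation 6713 of the 8071 called genes were called again. Of the 1731 called at least 2-fold, 1273 were called again at that size. No scaling moved the median of all genes by 0.1 on the log2 scale. Each scaling sets the libraries relative to each other, which keeps the bulk of genes near no change. The median therefore cannot show a change in the amount of RNA per cell. The number of lists was 0 with an estimated correlation and 30 by fry, against 12 in camera with the preset correlation; fry does not compare a list with other genes. Of the 175 named genes and list members, 172 passed the main test, and most were picked by the size of their change. Their values were therefore likely to keep their side, and the next counts do not measure how well calls hold over all genes. Of 3150 values of these 175 genes under the alternatives, 3129 kept their side of the threshold. Of the others, 18 lost their call, 3 gained one and 0 reversed. The losses fell on 7 genes. Of 696 list values, 649 kept their side, 20 lost a call, 27 gained one and 0 reversed. Among the gene and list values that kept their side were 33 that changed sign and passed in neither setting. The replicate numbers gave no sign of pairing the samples: the deviations of same-numbered libraries from their group means correlated at -0.05, -0.15 and 0.04, and not every sample correlated best with its own number. With so few libraries per group this cannot exclude pairing. With the replicate block, 7772 genes changed (3931 rose and 3841 fell), of which 1460 rose and 271 fell at least 2-fold; besides the unfolded protein response list it changed no call among named genes and lists.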

Other observations

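The tests on markers of other cell types and on adjacent genes were chosen only after the results were seen. The marker test is the fourth form tried: the first rested on a single transcript that T cells also hold, the second on markers picked after their values were known, and the third on a bound that the B cell list met exactly and did not meet with a minimum count of 50. The remaining tests below were fixed before the values they measure were seen. Conditions on left-out libraries and on the interval of a share were not part of the rules as fixed.

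Several metabolic and stress lists moved in both directions. Of 24 glycolysis genes, 9 rose and 8 fell (camera adjusted p = 0.666): the glucose transporter gene Slc2a3 rose from 4181 ± 121 to 8807 ± 448 (SD, n = 3) and Eno2 from 119 ± 7.81 to 444 ± 26.7, while Pfkl fell from 8456 ± 197 to 4736 ± 73.7. The median of this list was 0.01 and turned negative under quantile normalisation (-0.05), after the GC and length correction (-0.03) and without DAHB replicate 2 (-0.00). Of 25 cholesterol synthesis genes, 13 fell and 6 rose (adjusted p = 0.167), with falls in Idi1 and Insig1 of -0.90 and -0.88 and a rise in Mvk of 0.70 on the log2 scale. Of 15 fatty acid synthesis genes, 8 fell and 2 rose (adjusted p = 0.0916; 0.0284 after the GC and length correction), and Scd1 fell from 4661 ± 161 to 2371 ± 238. Of 25 fatty acid oxidation genes, 8 rose and 9 fell (9 and 9 adjusted over the list alone; adjusted p = 0.988), with a median and a mean of 0.02 although the test pointed down; the median was -0.02 after the GC and length correction and -0.01 without NaCl replicate 2. Cpt1a, the entry step of fatty acids into mitochondria, rose by 0.67, and Oxct1, a ketone body enzyme, fell from 10822 ± 37.2 to 6612 ± 394. Of 21 NRF2 and glutathione targets, 8 rose and 7 fell (adjusted p = 0.913), and Gclc fell by a log2 fold change of -1.05. Of 20 nutrient transporters, 5 rose and 12 fell (13 fell adjusted over the list alone; adjusted p = 0.126), and the amino acid transporter genes Slc7a11 and Slc7a6 fell by log2 fold changes of -0.86 and -0.84 while Slc16a10 and Slc2a3 rose by 1.11 and 1.07. Of 36 lysosome and autophagy genes, 14 rose and 16 fell (adjusted p = 0.953), with a median of -0.06 and a mean of 0.07; Ctsz rose by 0.99 and Flcn fell by a log2 fold change of -0.94.

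Of 42 interferon-stimulated genes, 15 rose and 12 fell (13 fell adjusted over the list alone; adjusted p = 0.676). The median of the list was -0.13 and the mean -0.12 while the test pointed up, and with a minimum count of 50 the median was 0.09. Under quantile normalisation 14 members rose and 18 fell. Gbp7 rose from 582 ± 54.9 to 1747 ± 147 and Zbp1 from 251 ± 15.9 to 703 ± 66.7. Of 11 osmotic stress and NFAT5 targets, 4 rose and 5 fell (adjusted p = 0.299), and Sgk1 rose by 0.77; Slc5a3, which overlaps Mrps6, was lower by a log2 fold change of -1.29. Of 16 heat shock genes, 5 rose and 6 fell (adjusted p = 0.400), with a median of -0.10 and a mean of 0.17, and under quantile normalisation 10 fell and 4 rose. Hspb1 rose from 11.1 ± 2.70 to 160.0 ± 15.0, and Hspa1b, which shares reads with a near-identical copy and is uncertain, was higher by 0.69. Of 16 BCL2 family genes, 5 rose and 6 fell (adjusted p = 0.724; median -0.08, mean 0.00): the pro-death genes Bmf and Bcl2l11 rose by 1.16 and 0.83, and Bax fell from 5881 ± 309 to 3503 ± 284. Lists with fewer than 5 tested members were not tested as lists. Of the erythroid list only Car2 was tested and it fell by a log2 fold change of -0.38. Of 3 tested gamma delta and innate-like T cell markers, Trdc fell from 168 ± 16.8 to 110 ± 11.5, and Sox13 and Klrb1f, of low abundance and chosen after their values were seen, rose by 2.15 and 2.06. Of the sex-linked list only Xist was tested (adjusted p = 0.957). Xist was called lower without DAHB replicate 1 (log2 fold change -0.27, adjusted p = 0.019) and was on average higher by 0.14 after the GC and length correction.

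With 3 against 3 libraries there are 10 splits, too few for a share under 0.05. Each split other than the real one mixes both treatments unevenly on either side. Part of the treatment difference therefore stays in its contrast, and the rest widens the spread within its groups. The counts of these splits are thus no level for chance. The real split gave 8071 changed genes and the highest other split 0, and it was the 1 split of 10 with as many. For changes of at least 2-fold the real split gave 1731 and the highest other 0, again 1 split of 10. For gene lists by camera the real split gave 12 and the highest other also 12, so 2 of the 10 splits gave as many.

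The first pattern was that 1459 genes rose at least 2-fold and 272 fell. An even background of reads, such as genomic DNA, would raise nearly all low genes, but 64.1% of genes with a mean count of 10 to 50 were higher in DAHB (1699 of 2652, 95% interval 62.2 to 65.9). After the GC and length correction the ratio of risers to fallers was 4.73, and among genes with a mean of at least 100, away from the floor of the table, it was 3.76, so neither accounts for the whole pattern, although changes of any size among the latter ran the other way (2887 rose and 3770 fell), the ratio was 1.64 from a mean of 2000 upwards, and quantile normalisation brought it to 1.61 over all genes. A candidate explanation is a response of the kind described for inhibitors of histone deacetylases, enzymes whose inhibition loosens chromatin. The 7 textbook genes of that response do not measure the excess of genes that rose at least 2-fold. Of these 7 genes, 6 changed in its direction. In 10000 lists matched on expression the median was 2, and 0.57% of the lists had as many as 6. These lists drew each gene by itself, whereas genes can change together, so 0.57% is no level for chance. The changes were modest, with H1f0, Cdkn1a, Glrx and Mt1 higher by 0.44, 0.34, 1.13 and 1.14 and Tyms and Ctps lower by log2 fold changes of -0.33 and -0.16, and the histone gene H2bc21 went the other way (-1.11), so this remains a hypothesis.

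The second pattern was the rise of 47 of 79 ribosomal protein genes with 0 falls. After the GC and length correction 43 rose, and the lowest number under quantile normalisation, equal totals and edgeR was also 43. At least 40 had been set beforehand as evidence against these explanations, and by that rule alone 43 counted against both. A look at each library left out was not part of the rule. With each left out the number ranged from 33 to 65, which is wider than the difference between 43 and 40. A trend with GC content or length, or the scaling between libraries, therefore cannot be told apart from a change in these mRNAs for part of the rise.

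The third pattern was that some markers of other cell types were higher in DAHB, although none of these lists passed camera in the main test. Of the B cell markers 55.6% rose, among them the class II genes H2-Aa, H2-Ab1 and H2-Eb1. These class II genes lie close together on chromosome 17, so they are not independent markers. In contrast 3 immunoglobulin genes fell: Ighm from 4344 ± 30.4 to 1610.1 ± 80.4, Ighd by a log2 fold change of -2.28 and Igkc from 26.6 ± 4.51 to 10.1 ± 7.46. With a minimum count of 50, 5 B cell markers rose and 1 fell, and without NaCl replicate 1, 5 rose and 2 fell. Of the myeloid markers 30% rose, close to the share of all tested genes that rose (4052 of 13804), and 3 rose without NaCl replicate 1; C1qb was at 159 ± 64.0 and 191 ± 58.0 (adjusted p = 0.371), and Cst3 fell, a call lost under quantile normalisation (log2 fold change -0.12, adjusted p = 0.0933). Of the stromal markers, with the epithelial gene Epcam among them, 41.7% rose, and Col1a1 was at 98.4 ± 38.8 and 112 ± 6.07 (adjusted p = 0.338). Sele, Ccn1 and Twist1, which are not among these tested markers, fell. For all 3 cell types a larger share cannot be told apart from expression in the T cells, since the markers moved unevenly and several were of low abundance.

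Log2 fold changes of adjacent genes were weakly correlated. Across 11421 pairs of adjacent, non-overlapping genes without a shared start of the symbol, Spearman's rho of the log2 fold changes was 0.0943, above the highest of 1000 shuffles of gene order (0.0308; p = 0.001, the smallest they can give). Genes are not independent replicates, and the correlation is small. It was 0.117 for pairs under 50 kb apart and 0.0480 for wider pairs. An example chosen after its values were seen is chromosome 17 (35194439 to 35205351), where Ltb, Tnf and Lta rose by 1.59, 2.60 and 3.15. Related genes that lie together were not separated from effects of position, and no explanation was tested.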
